A study of Homo sapiens with 8 samples.

How the data were processed

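Total RNA from cultures of A549, a human lung adenocarcinoma cell line, was profiled for microRNAs (miRNAs) on 8 one-colour Agilent arrays. Per the labels, 4 cultures received 2 Gy of gamma-rays at 2.8 Gy per minute and 4 non-irradiated cultures were handled alike (0 Gy), and RNA was extracted after 4 h. Per the labels' protocols, only RNA with an integrity number of at least 6 was used, and 200 ng was labelled with Cy3. The labels call the samples of a group biological replicates, so the p-values rest on separate cultures as far as the labels say.

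Files of 2 kinds were used. The first kind was 1 scanner file per sample, written by Agilent Feature Extraction 12.0.0.7 per the file headers. It holds fluorescence intensity on a linear scale for each spot, after local background subtraction and spatial detrending and with no normalization between arrays, together with deposited 0 or 1 quality flags per spot. The second kind was a table of processed intensity values that the authors deposited for the whole series, covering 311 miRNAs. Its values were linear and uncentred, with column medians between 12.0 and 16.4, and they ran in the direction of the scanner intensities. The normalization between arrays behind them is not given in the sources used here. Tested on the files, its miRNAs were exactly those that Feature Extraction called detected on at least 5 of the 8 arrays, and its empty cells marked miRNAs not detected on the matching array.

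Each array carried 50980 spots outside the controls, which stood for 2549 human miRNAs through 5893 probes. Control spots and spots called outliers by the scanner software were left out, between 1506 and 1631 spots per array, and no spot was saturated. The remaining spots of a probe were averaged. A probe counted as detected on an array when at least 0.5 of its spots were well above background. Each array was divided by the 75th percentile of its signal over the 366 probes detected on all 8 arrays, because most probes of a miRNA array lie near background, and was then multiplied by 1 common factor. Scaled signals were raised to a floor of 15.2, the lowest scaled signal of any detected probe, and then put on the log2 scale. A fold change against a group at the floor therefore understates the difference. The brightest probe stood for a miRNA. Among 154 tested miRNAs with more than 1 probe detected on all arrays, the probes of 7 had fold changes of opposite sign. Total signal was not used for scaling, since miR-7975 and miR-7977 alone made up 59.5% to 71.1% of the summed signal of an array. The number of arrays, 4 per group, limits the precision of every comparison.

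Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A miRNA was tested when it was detected on all arrays of at least 1 group. For a miRNA not well above background on any array of a group, a bound on the fold change was computed beside the limma test, as the mean of the other group over the higher of each dim array's lowest detected signal and the probe's own signal. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, where a list had at least 3 tested members. Detected miRNAs per array, the 75th percentile and the summed signal were compared by exact two-sided permutation tests, in which 4 arrays against 4 can give no p below 0.0286. Correlations and outliers were computed in Python 3.11.15 with NumPy 2.4.6. Of the 247 miRNAs tested, 243 had a hairpin gene symbol of the same name in the RefSeq table of assembly GRCh38.p14. The array's own layout refers to another assembly, so no coordinates were used and miRNAs keep the names of the scanner files.

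Before the data were examined, 12 lists of miRNAs were fixed: p53-responsive miRNAs, the let-7 family, the miR-17-92 clusters, the miR-200 family, miRNAs targeting DNA damage response genes, miRNAs processed through KSRP, stress-induced miRNAs, the miR-15/16, miR-23/27/24, miR-29 and miR-30 families, and GC-rich or fragment-derived entries as a sign of RNA quality. Fixed with them were 7 lists of markers of other cell types. The rule for the miRNAs named in the text was fixed at the same time. It took every miRNA past the threshold if 25 or fewer passed, and, where fewer than 12 passed, the 8 higher and 8 lower miRNAs with the smallest p. It also took up to 4 tested members of each list (2 by signal and 2 by p), the 10 with the highest signal in non-irradiated cells, 6 miRNAs of prior interest (miR-34a, let-7a, let-7g, miR-21, miR-24 and miR-210), and miRNAs detected on all arrays of 1 group and on none of the other.

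The table and the scanner files did not carry the same labels. Every table column was set against every scanner file, by its empty cells and by the SD of the log2 ratio to the total signal per miRNA. Each column had 1 best scanner file with 0 differing empty cells and an SD of 0.10 to 0.30, against 0.25 or more for the next file. That file belonged to the same sample for 2 columns and to another sample for 6, of which 4 were of the other group. The 2 columns without empty cells rested on the SD alone, 0.18 against 0.25 and 0.17 against 0.26. Which deposit carries the right labels cannot be settled from the files. The labels of the scanner files were kept for the comparison fixed before the data were examined. The labels that each array carries in the table were used as a second assignment, added after the mismatch was seen, on the same scanner intensities so that the label is the only difference.

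Replicate numbers are shared by the groups in the labels. Under the table's labels, same-numbered arrays deviated together from their group means, with correlations across miRNAs of 0.81, 0.61, 0.73 and 0.49, all above 0.1, although non-irradiated replicate 4 correlated better with an irradiated array of another number (0.65), so a fit with the replicate number as a block was run beside the unblocked one. Under those labels same-numbered arrays also lay next to each other on the slide, with the non-irradiated array in column 1 or 3 and the irradiated array in column 2 or 4. Under the scanner files' labels the same check did not hold for every pair, and its values are given with the alternatives.

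Alternatives fixed before the data were examined were other scalings (75th percentile over all probes, quantile, median, none), normexp background correction with an offset of 50, other summaries of the probes, other filters and detection flags, a lower floor, eBayes with trend and robust, array weights, the replicate block, the processed table's values, and leaving out each array in turn. Normexp was designed for mean spot signals and was run on median spot signals, the ones used from the files. Simulated data with the measured means and spreads were used for the unblocked fit under both sets of labels and the blocked fit under the table's labels. No recovery is given for the other alternatives. In each run 40 miRNAs were changed, 20 by each of 2 sizes, and false calls averaged 1.2, 1 and 1.6 per run. Of miRNAs changed 2-fold, 92% were recovered under the scanner files' labels (247 miRNAs), 86% under the table's labels (228 miRNAs) and 97.5% with the block under the table's labels. Of miRNAs changed 1.41-fold, the shares were 39.5%, 29% and 77.5%.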

Results

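The study asked how the miRNAs of A549 lung adenocarcinoma cells responded 4 h after 2 Gy of gamma-rays, the daily dose of conventional fractionated radiotherapy. Signals of 2549 human miRNAs were measured on 8 arrays of 1 slide, 4 labelled non-irradiated and 4 labelled irradiated. Between 220 and 298 miRNAs were detected per array, and the 75th percentile of the signal lay between 170 and 297 intensity units. The number of arrays limits the precision of each value.

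The 2 deposits of these arrays assigned them to different samples. By their values and empty cells, 6 of the 8 columns of the processed table held the array that the scanner files gave to another sample, and 4 of these crossed between the groups. Under the scanner files' labels the 4 non-irradiated arrays filled row 1 of the slide and the 4 irradiated arrays row 2, so row and group cannot be told apart there. Under the processed table's labels each row held 2 arrays of each group, but the non-irradiated arrays filled slide columns 1 and 3 and the irradiated arrays columns 2 and 4, so group and these columns cannot be told apart there. Results are therefore given under both sets of labels, with "labelled" marking that the group is the one a deposit states.

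Whatever the labels, the 8 arrays gave 1 picture of which miRNAs were measurable in these cells. All 9 members of the let-7 family, which restrains growth-promoting genes such as RAS, were detected on at least 1 array, and 8 of them on all 8 arrays. All members of the miR-23/27/24 clusters (5), the miR-30 family (5) and the miR-29 family (3) were detected on all 8 arrays, as were 9 of the 12 members on the array of the proliferation-linked miR-17-92 clusters. Of 17 p53-responsive miRNAs, 8 were detected on all 8 arrays, among them miR-34a-5p, miR-192-5p, miR-194-5p and miR-215-5p, while miR-34b and miR-34c were not well above background on any array. None of the 5 members of the miR-200 family, which maintains the epithelial state in many tissues, was well above background on any array. Of the 10 stress-induced miRNAs, miR-21-5p, miR-31-5p, miR-221-3p and miR-222-3p were detected on all 8 arrays and the hypoxia-induced miR-210-3p on 5, whereas miR-146a-5p and miR-155-5p were detected on none. For the fixed markers of blood cells (7 on the array), fibroblasts and smooth muscle (8), striated muscle (6), liver (1) and pluripotent cells (7), no member was well above background on any array. The endothelial marker miR-126-3p and the neural marker miR-128-3p were each detected on 1 array.

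The miRNAs named for their signal were miR-7975, miR-7977, miR-21-5p, miR-5100, miR-7641, miR-1260b, miR-494-3p, miR-4284, miR-1260a and miR-8069. Brightness also depends on the probe, so these values do not order the miRNAs by amount. The scaled signal of miR-21-5p, an miRNA raised in many carcinomas, was 12106 ± 2081 on the arrays labelled non-irradiated in the scanner files and 12501 ± 1536 on those labelled irradiated (SD, n = 4 each). The log2 fold changes of all 10 under those labels lay between -0.47 for miR-1260b and 0.41 for miR-494-3p, none past the threshold.

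Under the scanner files' labels, 6 miRNAs were higher on the arrays labelled irradiated and none was lower, among 247 tested with limma and Benjamini-Hochberg adjustment. The largest difference was that of miR-4697-5p, with a log2 fold change of 1.28 ± 0.24 (SE, adjusted p = 0.00299), from 24.8 ± 12.5 to 55.9 ± 7.35 (scaled signal, SD, n = 4 each). It was followed by miR-513a-5p, of an X-linked miRNA cluster, with 1.12 ± 0.21 (adjusted p = 0.00299), from 54.8 ± 18.2 to 115 ± 15.2. The log2 fold changes of miR-4313, miR-6769b-5p and miR-3652 were 1.04 ± 0.23, 0.91 ± 0.21 and 0.90 ± 0.21, with adjusted p-values in limma of 0.0141, 0.0149 and 0.0152. The difference for miR-1973, one of the fixed entries described as RNA fragments, was 0.79 ± 0.21 (adjusted p = 0.0415), from 309 ± 117 to 510 ± 33.9. In all but miR-4313 the lowest array labelled irradiated lay above the highest labelled non-irradiated. Over the 205 miRNAs detected on all 8 arrays, a choice made without the labels, the groups were parted in this way, in either direction, for 10 (4.88%), where chance gives 2.86%. The filter behind the 247 did use the labels, so it could admit a miRNA through the group in which it was brighter. With the test limited to the 205, 4 passed the threshold in limma, 3 of them among the 6. miR-4697-5p, miR-4313 and miR-3652 were not among the 205. With detection on at least 1 array as the filter, 0 of 319 passed.

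Detection differed for some of the miRNAs past the threshold. miR-4697-5p, miR-4313 and miR-3652 were well above background on 4 of 4 arrays labelled irradiated and on 1 of 4 labelled non-irradiated, replicate 3, so their fold changes rest in part on signals near the floor. They entered the test only through their detection on the arrays labelled irradiated, the group in which they were higher. The second probe for miR-4697-5p was detected on no array. The second probes for the other 5 had log2 fold changes of 0.59 for miR-513a-5p and 0.54 for miR-1973, below those of the brightest probes, 0.89 for miR-4313, 0.93 for miR-6769b-5p and 0.98 for miR-3652. Detected on all 4 arrays labelled irradiated and on none labelled non-irradiated were miR-17-3p, miR-324-5p, miR-4484 and miR-6807-5p, none past the threshold in limma. The bound was at least 1.04-fold for miR-17-3p and miR-6807-5p and gave no fold for the others. More miRNAs were detected on the arrays labelled irradiated, 275 ± 22.3 against 234.5 ± 13.5 (SD, n = 4 each), a difference that did not reach the threshold (exact permutation p = 0.0571, two-sided). The 75th percentile was 269 ± 34.7 against 217 ± 45.7 (exact permutation p = 0.143) and the summed signal 54876 ± 5007 against 47799 ± 4273 (exact permutation p = 0.114).

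Values that missed the threshold are given for orientation. Among miRNAs with higher means on the arrays labelled irradiated, miR-6785-5p had a log2 fold change of 0.98 ± 0.27 and miR-5699-5p of 0.84 ± 0.23 (both adjusted p = 0.0510 in limma). On the lower side, miR-4497 was at -0.64 ± 0.20 (adjusted p = 0.102), and miR-6803-5p, miR-5001-5p, miR-4443, miR-4516, miR-1260b, miR-4507 and miR-125b-5p lay between -0.54 and -0.44. The p53 target miR-34a-5p was at 0.18 ± 0.19 and miR-210-3p at 0.33 ± 0.18. The latter was detected on 4 of 4 arrays labelled irradiated and on 1 of 4 labelled non-irradiated, so its value rests in part on signals near the floor. For let-7a-5p the value was 0.11 ± 0.20, for let-7g-5p -0.17 ± 0.19, for miR-21-5p 0.06 ± 0.17 and for miR-24-3p 0.02 ± 0.16 (log2, SE).

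The count of 6 depended on single arrays. It was 0 without irradiated replicate 2 (lowest adjusted p = 0.0976 in limma), 2 without irradiated replicate 4, 25 without non-irradiated replicate 2 and 43 without non-irradiated replicate 3. The log2 fold changes of the 6 kept their sign whichever array was left out, from 0.66 to 1.02 for miR-1973 and from 1.09 to 1.59 for miR-4697-5p. The count of calls thus moved more than the fold changes. The count was also 0 when only the 4 arrays with the same group in both deposits were kept (limma, 8 of 254 miRNAs at an unadjusted p under 0.05), a comparison added after seeing the data. There 2 arrays stood against 2, log2 fold changes still reached 1.27 in size, and slide row and group again coincided. The call for miR-1973 was the least stable of the 6, kept in 10 of 26 alternative settings, lost in 14 and of the other sign in 2, while each of the others was kept in 15 to 19 of 24 or 26.

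**Figure D1:**
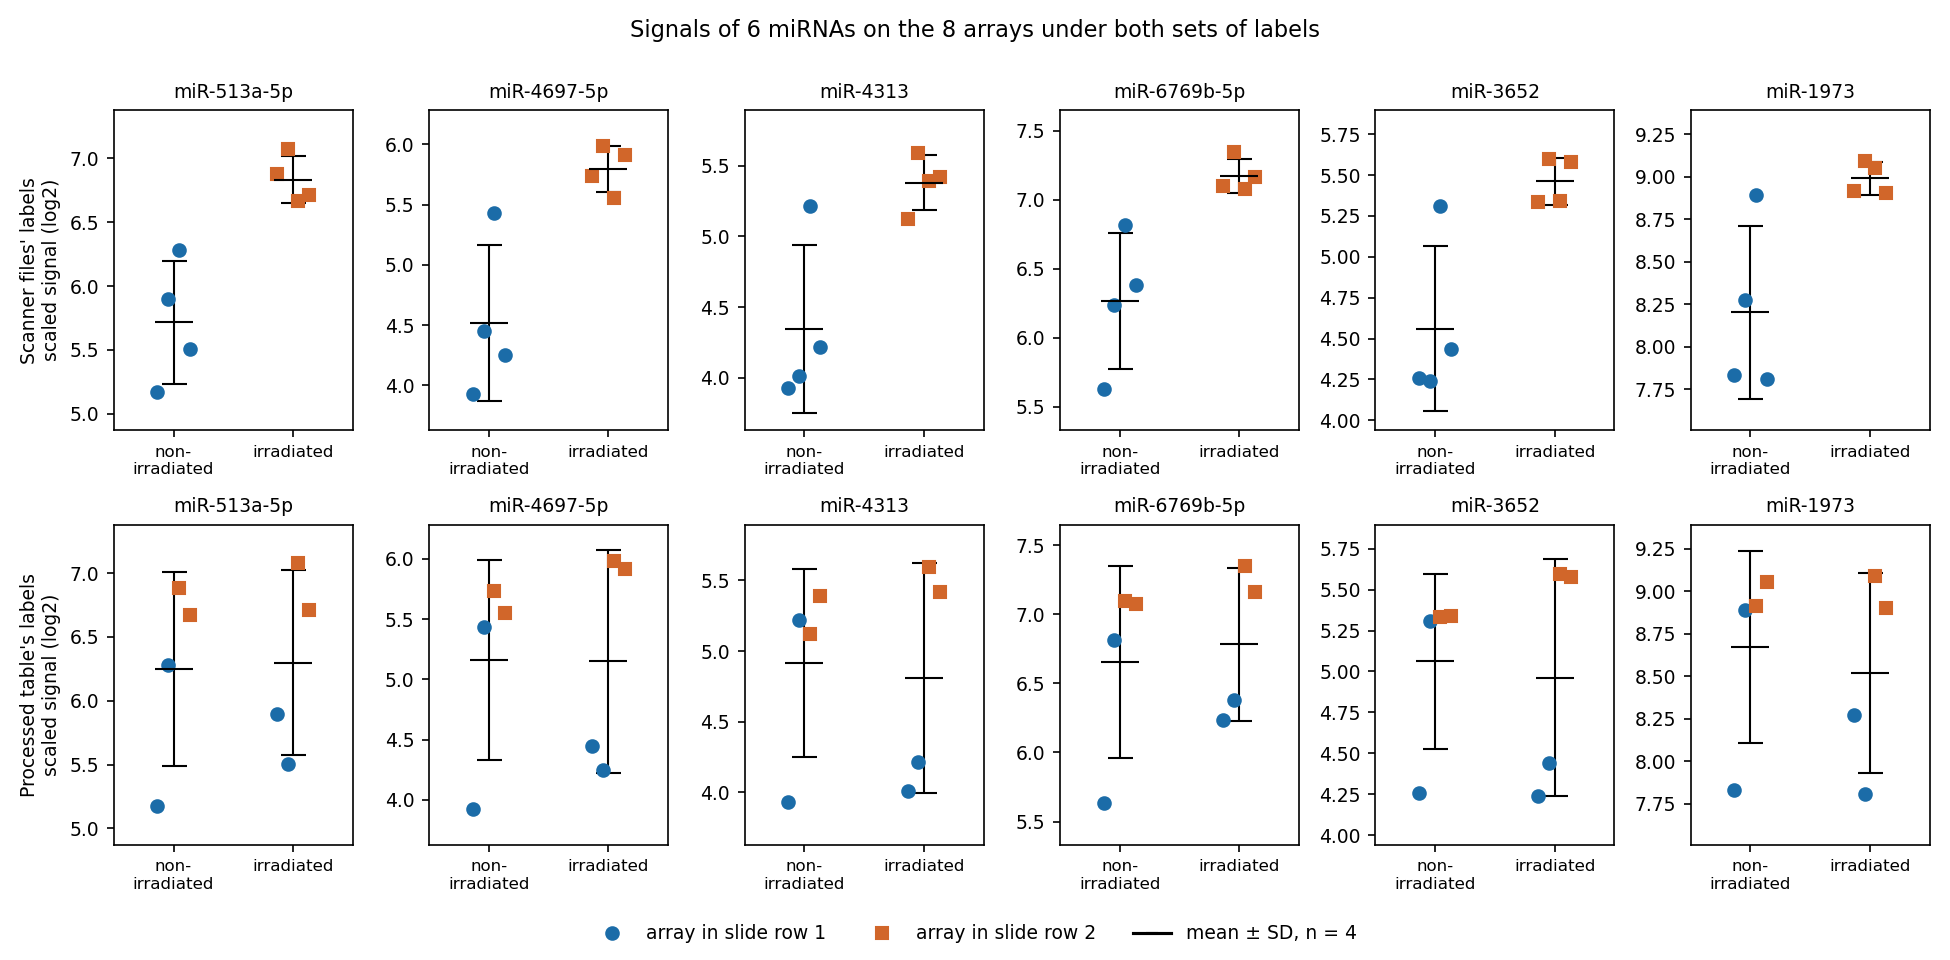
Scaled signal (log2 of intensity units) of 6 miRNAs on each of the 8 arrays, grouped by the scanner files' labels in the top panels and by the processed table's labels in the bottom panels, with circles for slide row 1, squares for slide row 2, and bars for the mean ± SD of 4 arrays. In the top panels each group holds 1 row of the slide and the means differ by 0.79 to 1.28, and in the bottom panels each group holds 2 arrays of each row and the means lie closer together than the SDs. A difference between rows cancels in the bottom means and enters the SDs, so the panels do not decide between the labels.

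Under the processed table's labels, no miRNA passed the test. Of 228 miRNAs tested on the same scanner intensities, 0 passed the threshold in limma with Benjamini-Hochberg adjustment (lowest adjusted p = 0.998), and 0 had an unadjusted p under 0.05. Of the 205 miRNAs detected on every array, the groups were parted for 0, where chance gives 2.86%. Each group held arrays of each slide row, so differences between the rows entered the spread that this test measures against. Taken alone, these counts of 0 are therefore not evidence that a response was absent. The largest log2 fold change among these 228 was 0.29 in size, and the 95% interval of a miRNA reached 0.43 to either side in the median. With the replicate number as a block, which compares arrays of the same slide row, 0 passed and 4 had an unadjusted p under 0.05. The processed table's own values for 311 miRNAs, with its own column labels, gave 0 past the threshold in limma and 1 at an unadjusted p under 0.05, with log2 fold changes of up to 0.87 in size. Of simulated 1.41-fold changes on the 228 miRNAs, 29% were recovered without the block and 77.5% with it. In these runs 40 of the 228 were changed at once, which eases the adjusted threshold, so the shares apply to that setting alone.

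The 6 miRNAs that were higher under the scanner files' labels did not differ beyond their spread under the table's labels. They were selected for a difference that is also one between slide rows. Under the table's labels each group held equal numbers of arrays from each row, so such a difference cancels and enters the spread. Small values follow from this layout whichever labels are right, so they do not decide between the labels. miR-513a-5p was at 0.05 ± 0.36, miR-6769b-5p at 0.13 ± 0.32 and miR-1973 at -0.15 ± 0.30 (log2 fold change, SE). miR-3652, miR-4313 and miR-4697-5p were not detected on all arrays of either group and were not tested there, with mean differences of -0.10, -0.11 and -0.01. The p53 target miR-34a-5p was at 0.12 ± 0.21 with a 95% interval from -0.33 to 0.58, and miR-22-3p at 0.27 ± 0.20 with an interval from -0.15 to 0.70. For let-7a-5p the value was -0.06 ± 0.22, for let-7g-5p -0.09 ± 0.21, for miR-21-5p 0.14 ± 0.18 and for miR-24-3p 0.09 ± 0.17. Of the 222 miRNAs tested under both sets of labels, 131 had fold changes of the same sign. That count was not tested against chance and miRNAs moved together across arrays, so no agreement between the labels is read from it. Detected miRNAs per array were 262 ± 20.0 on the arrays labelled non-irradiated and 248 ± 35.3 on those labelled irradiated (exact permutation p = 0.514).

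**Figure D2:**
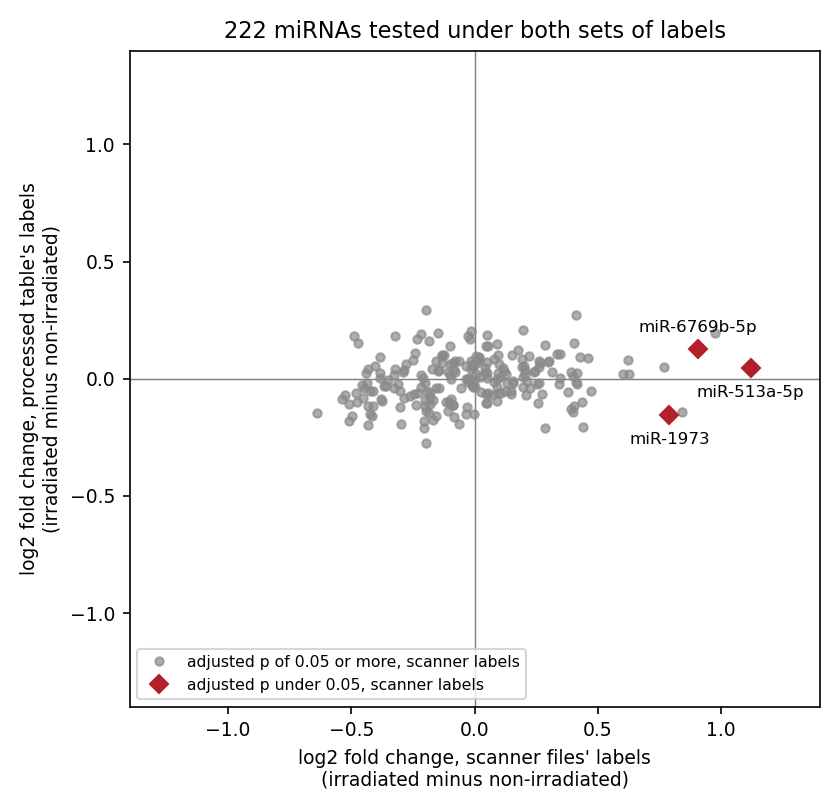
Log2 fold change, irradiated minus non-irradiated, of the 222 miRNAs tested under both sets of labels, with the scanner files' labels on the x axis and the processed table's labels on the y axis. Diamonds mark miR-513a-5p, miR-6769b-5p and miR-1973, which lie between 0.79 and 1.12 on the x axis and between -0.15 and 0.13 on the y axis. A difference between slide rows cancels on the y axis, so these positions do not decide between the labels.

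No list of miRNAs passed its test under either set of labels. Under the scanner files' labels, 0 of 11 lists with at least 3 tested members passed with camera, fry or fry's test for changes in either direction (camera adjusted p = 0.919 for every list, and adjusted p = 0.949 with an estimated correlation). At an unadjusted p under 0.05 the counts were 0 for camera with either correlation, 0 for fry and 3 for fry's test for changes in either direction. Among the 17 tested GC-rich or fragment-derived entries, only miR-1973 passed the threshold, and 1 passed adjusted over the list alone. The median log2 fold change of that list was -0.21 and its mean -0.03. miR-494-3p was at 0.41 ± 0.21 and miR-1275 at 0.62 ± 0.22 (SE), neither past the threshold.

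In each of the other 10 lists, 0 members passed over all tested miRNAs and 0 adjusted over the list alone. The 8 p53-responsive miRNAs had a median of 0.10, with miR-22-3p at 0.41 ± 0.17, miR-107 at 0.09 ± 0.17 and miR-16-5p at -0.20 ± 0.18. The 8 tested let-7 members had a median of 0.11, with let-7e-5p at 0.26 ± 0.22 and let-7i-5p at -0.22 ± 0.18, and the 14 miRNAs processed through KSRP a median of 0.05. The 10 members of the miR-17-92 clusters had a median of -0.04, with miR-18a-5p at 0.47 ± 0.16, miR-19b-3p at 0.02 ± 0.16 and miR-20a-5p at -0.18 ± 0.18. The 8 miRNAs targeting DNA damage response genes had a median of 0.03, with miR-503-5p at 0.35 ± 0.16 and miR-100-5p at -0.28 ± 0.17. The 5 stress-induced miRNAs had a median of -0.08, with miR-31-5p at -0.10 ± 0.17 and miR-222-3p at -0.22 ± 0.18. The medians were -0.15 for the miR-30 family (5 members, miR-30c-5p at -0.46 ± 0.19), -0.02 for the miR-15/16 family (5 members, miR-15b-5p at -0.06 ± 0.21), 0.05 for the miR-29 family (3 members, miR-29b-3p at 0.05 ± 0.18) and 0.00 for the miR-23/27/24 clusters (5 members, miR-27a-3p at -0.06 ± 0.18). The other named members, let-7f-5p, miR-20b-5p, miR-27b-3p, miR-23a-3p, miR-23b-3p, miR-29a-3p, miR-29c-3p, miR-30a-5p and miR-30b-5p, lay between -0.20 and 0.07. All these fold changes are on the log2 scale with their SE.

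Under the processed table's labels, 0 of 11 lists passed with camera, camera with an estimated correlation, fry or fry's test for changes in either direction, and 0 members passed in any list over all miRNAs or adjusted over the list alone. At an unadjusted p under 0.05 camera called 1, and camera with an estimated correlation and both forms of fry called 0. The smallest camera p-values were those of the stress-induced miRNAs (4 tested, median 0.08) and the p53-responsive miRNAs (8 tested, median 0.03), with unadjusted p-values of 0.0347 and 0.0684 and an adjusted p of 0.376 for both (adjusted p = 0.911 with an estimated correlation). The medians were -0.04 for the let-7 family (8 tested), -0.02 for miRNAs processed through KSRP (13), 0.00 for the miR-17-92 clusters (9), 0.03 for miRNAs targeting DNA damage response genes (6), -0.04 for the miR-15/16 family (4), 0.08 for the miR-23/27/24 clusters (5), 0.04 for the miR-29 family (3), -0.01 for the miR-30 family (5) and 0.01 for the GC-rich or fragment-derived entries (17, with a mean of -0.01). With the preset correlation, but not with an estimated one, leaving out 1 array called up to 7 lists. The calls were 6 without non-irradiated replicate 1, 3 without irradiated replicate 1, 7 without non-irradiated replicate 2 and 1 without irradiated replicate 4.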

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

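The tests of explanations for the 6 miRNAs were chosen after the results were seen. So was every comparison under the processed table's labels except the unblocked one on that table's own values.

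The 6 miRNAs that were higher on the arrays labelled irradiated in the scanner files are a pattern whose source is open. Of 35 splits of the 8 arrays into 4 and 4, 1 gave as many as 6 past the threshold, the split by the scanner files' labels. The highest of the others gave 5, and 1 of 35 is the smallest share these splits can give. Chance is therefore not excluded for the count of 6, which was 0 without irradiated replicate 2. At an unadjusted p under 0.05 the split by these labels had 60 miRNAs and did not stand apart, since 4 of the 35 splits, itself included, had as many, and the split between slide columns 1 and 2 and columns 3 and 4 had 99. Labels crossed in 1 of the deposits may be the source, since same-numbered arrays correlated at 0.49 or more under the processed table's labels and as low as 0.04 under the scanner files' labels, yet under the table's labels same-numbered arrays were also neighbours on the slide and the array of 1 number correlated better with another number (0.65). Position on the slide cannot be told apart from a response to 2 Gy under the scanner files' labels, since all 4 arrays of row 1 carried the label non-irradiated. Under the processed table's labels, row 1 held replicates 1 and 2 of both groups and row 2 held replicates 3 and 4. A difference between rows may then also be one between cultures or RNA preparations, untested. No value here separates these explanations.

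A test for arrays far from the other 3 of their group was run on 126 sets of 4 arrays under the scanner files' labels, over 3 array totals and the named miRNAs, and 4 sets were past Dixon's critical value, where chance gives about 1 in 20 or 6.30. Irradiated replicate 4 had the low value of miR-20a-5p (183 against 218 to 226), miR-210-3p (18.9 against 25.8 to 26.5) and miR-30b-5p (75.1 against 95.5 to 100.1). Irradiated replicate 3 had the low value of miR-5699-5p (52.9 against 62.5 to 63.5). All are scaled signals.

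One labelling spike-in that the comparisons did not use differed between the groups of the processed table, which coincide with slide columns 1 and 3 against 2 and 4, so irradiation and column cannot be told apart. Its log10 signal was 2.30 ± 0.03 on the arrays labelled non-irradiated and 2.42 ± 0.06 on those labelled irradiated (SD, n = 4 each), a difference of 0.123, higher in 4 of 4 same-numbered pairs (exact permutation p = 0.0286, two-sided, the smallest 4 against 4 can give, and adjusted p = 0.0571 over the 2 labelling spike-ins). The other was 2.78 ± 0.07 against 2.92 ± 0.10, also higher in 4 of 4 pairs (exact permutation p = 0.0571). Under the scanner files' labels the first differed by -0.07 (exact permutation p = 0.229) and the other by -0.12 (exact permutation p = 0.171).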

How the results depend on the processing

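Tests under the processed table's labels, within slide rows and on the 4 arrays with the same group in both deposits were chosen after the data were seen. Only the unblocked test of that table's own values was fixed before. Under the scanner files' labels, the 6 calls became 57 with no scaling between arrays (which moved the median of all miRNAs by 0.32, and all 57 were higher), 22 with total signals per miRNA and Feature Extraction's own detection flag (306 tested), 90 with array weights (69 higher, 21 lower), and 0 with a filter of detection on at least 1 array, with no filter, with that flag alone, with the processed table's values, with the arrays assigned as in that table and with only the 4 arrays of the same group in both deposits. In limma 60, 56, 62, 1, 0 and 8 miRNAs had an unadjusted p under 0.05 in those 6 settings. With no filter 2549 miRNAs were tested and most sat at the floor with no spread, and elsewhere the cause was not tested. The 75th percentile over all probes moved the median by 0.49 and gave 9 calls. Leaving out 1 array gave 0 to 43. In 12 settings, the 75th percentile over all probes included, the count stayed within 1.5 times of 6. The calls themselves changed with normexp (7 calls, 1 of them lower), which kept 3 of the 6. Detection on all 8 arrays (4 calls) kept the 3 of the 6 that it tested. It left out miR-4697-5p, miR-4313 and miR-3652, detected on 5 arrays each. Under the table's labels the count was 0 in all 28 settings. With the replicate number as a block, 28 miRNAs passed (18 higher, 10 lower) under the scanner files' labels, where same-numbered arrays correlated at 0.38, 0.60, 0.04 and 0.60 1 of these under 0.1, so the numbers are not taken to pair the arrays, and not every array did so best with its own number under either set of labels. The block changed no call under the table's labels, where it gave 0, the table's values included. Slide and scan date were not run as blocks, since there was 1 slide and 1 scan. The log2 fold change of miR-1973 became -0.19 with the table's values and -0.15 with its assignment, and that of miR-4313 became -0.092 with the table's values, where the values differ as well as the labels, while with the assignment only the labels and the tested miRNAs differ. With that assignment the difference in detected miRNAs became -14 and that in the 75th percentile -13.7. Leaving out 1 array under the scanner files' labels gave differences of 32.8 to 50.2 in detected miRNAs and of 36.9 to 68.9 in the 75th percentile. The first had an exact permutation p of 0.0286 without irradiated replicate 2, and the summed signal differed by 4970 to 8592. List tests called 0 in all 26 settings under the scanner files' labels, and under the table's labels 0 to 7 without 1 array, 1 within slide row 1 (p53-responsive) and 1 within slide row 2 (KSRP-processed), none with an estimated correlation, where the cause was not tested. Of the values for single named miRNAs, 1251 kept their side of the threshold or moved by less than the spread between replicates, 80 passed newly, 54 passed no longer, 3 that passed in either setting turned sign, and 151 that passed in neither moved by more, 78 of them to the other sign, as did 96 of the 1251. Signal over background limits miRNAs near the floor, among them miR-4697-5p, miR-4313 and miR-3652.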

Other observations

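The pattern described here was noticed in the data, and all its tests were chosen after it was seen. The largest difference among the arrays ran across both groups. Over the 205 miRNAs detected on all 8 arrays, the first principal component held 52.1% of the variance and the second 34.2%. On the first, miR-215-5p and miR-192-5p (both p53-responsive), miR-224-5p and the let-7 members let-7d-5p, let-7e-5p and let-7f-5p lay at one end, and miR-5787, miR-6891-5p, miR-6785-5p and the GC-rich miR-1268a at the other. The first also separated slide columns 1 and 2 (-3.65 to -1.22) from columns 3 and 4 (0.06 to 5.26). The second separated the rows of the slide (0.87 to 3.34 against -2.98 to -1.46), which is also the split by the scanner files' group labels.

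The median of the let-7 family and that of the GC-rich or fragment-derived entries shifted against each other from array to array. On non-irradiated replicates 1, 2, 3 and 4 of the scanner files the median deviations were 0.37, 0.33, -0.39 and -0.40 for let-7, 0.33, 0.15, -0.50 and -0.12 for p53-responsive miRNAs, 0.41, 0.14, -0.36 and -0.13 for the miR-15/16 family and 0.32, 0.17, -0.35 and -0.13 for the miR-23/27/24 clusters. The list processed through KSRP, which shares members with let-7, was at 0.37, 0.26, -0.35 and -0.18. The other 5 lists stayed between -0.25 and 0.23 on these arrays, and on replicate 4 the miR-30 family (0.07), the miR-17-92 clusters (0.01) and the stress-induced miRNAs (0.03) lay on the other side from let-7. Over the 8 arrays the let-7 and GC-rich medians had a Pearson correlation of -0.94 (exact permutation p = 0.000521, adjusted p = 0.0026 over 5 relations computed) and a Spearman correlation of -0.93 (exact permutation p = 0.00223), and Pearson's value was -0.87 without the 2 arrays farthest from the median. This correlation held only after scaling between arrays. Without scaling Pearson's value was 0.15 (exact permutation p = 0.714), Spearman's 0.07 (exact permutation p = 0.882) and Pearson's without the 2 farthest arrays -0.34, computed apart from the 5, so nothing is read from it, while the difference of the medians is the same with and without scaling. Each row of the slide holds 4 arrays, so no correlation within rows is given. The let-7 median minus the GC-rich median ranged from -0.84 (non-irradiated replicate 3 of the scanner files) to 0.63 (non-irradiated replicate 2). It correlated at -0.35 and -0.05 with 2 stringency ratios and at 0.07 and -0.19 with 2 labelling spike-ins, with exact permutation p-values of 0.400, 0.906, 0.857 and 0.639 and Spearman correlations of -0.43, 0.24, 0.14 and -0.19 (adjusted p = 0.906 for each Pearson value). Without the 2 farthest arrays Pearson's values were 0.07, 0.63, 0.02 and -0.40.

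No scaling factor can move the difference of the medians, so its spread over the arrays does not come from scaling. The SD of the difference was 0.54, against 0.25 at the 95th percentile of 10000 random pairs of lists of the same sizes. That comparison decides nothing, since the lists were picked after they were seen to move apart. Random lists are also drawn without regard to whether their members move together, as those of let-7 and the GC-rich entries did (estimated correlations 0.94 and 0.74, scanner files' labels). Irradiation does not account for most of the difference of the medians, since 2.34% of its variance lay between the groups under the scanner files' labels and 0.0917% under the processed table's labels. Position along the slide may be the source of the difference, since 69.0% of its variance lay between slide columns 1 and 2 (0.24 to 0.63) and columns 3 and 4 (-0.84 to 0.08, exact permutation p = 0.0286, the smallest possible). These columns lay far apart in slide row 1 (0.60 and 0.63 against -0.84 and -0.65) and less so in row 2 (0.28 and 0.24 against 0.08 and -0.23). Columns cannot be told apart from replicate numbers under either set of labels. Columns 1 and 2 held replicates 1 and 2 of both groups in the scanner files' labels and replicates 1 and 3 in the processed table's. Differences between cultures or RNA preparations therefore stay open, untested.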
